A study of Mus musculus with 4 samples.

How the data were processed

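The series measured DNA binding of PU.1, an ETS-family transcription factor encoded by Spi1, by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse splenic B cells. The cells were purified by negative selection and cultured for 4 days (96 h) with lipopolysaccharide at 5 ug/ml and interleukin-4 at 10 ng/ml. They were fixed with 2% formaldehyde and sonicated, and libraries were read on an Illumina Genome Analyzer IIx, per the labels' protocols. There were 4 samples: a PU.1 immunoprecipitation from each of 3 genotypes (wild type, PU.1 knock-in and miR-155 knockout) and 1 input DNA sample. The sample titles call each immunoprecipitation a mix, and the labels do not say what was mixed.

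The authors deposited 1 peak list per immunoprecipitation, giving chromosome, start, end, a peak name and a score for each peak. Per the submitters' processing notes, Trim Galore, Bowtie and MACS were used, with the mouse build mm9. Their versions and settings, and whether the input sample served as the control for peak calling, are not given in the sources used here. The score has no stated definition. Its lowest value was 50 in the deposited wild-type list, 50.1 in the knock-in list and 50.2 in the knockout list, which is the form of the MACS version 1 score (a multiple of the −log10 p-value of the peak), but no label or header says so. A score of that kind grows with read depth as well as with enrichment. The authors' scores were therefore used only to rank, filter and describe peaks within 1 list, with few exceptions. A threshold setting applied the median wild-type score to all 3 lists, and score ranges of wild-type and knock-in classes were set side by side. Lists were called per sample, so replicate agreement could not be assessed.

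Coordinates are given on mm9 and counted from 1; 1 was added to each deposited start. The last peak on chromosome 1 ended at 197028196, beyond the last annotated gene of that chromosome in GRCm38, which ends at 195291439. The gene table at hand is of GRCm38, so it was not used to place peaks. Gene names, promoter and exon positions, PU.1 motif counts and the fixed lists of B cell, plasma cell, myeloid, T cell and control genes were planned for mm9 and were not analysed here. Which gene each region lies in is therefore not stated.

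Peaks of different lists were called shared when they overlapped by at least 1 bp. For each share, an exact (Clopper-Pearson) 95% binomial interval was computed; it covers counting error over peaks only and not the variation between mice or libraries. The overlap given by placement alone was estimated from 1000 circular shifts of the other list within each chromosome, using the last called position on the chromosome as its length. Regions were formed by joining overlapping peaks across lists. Peaks were divided into 10 equal classes by score within their list. Scores of shared and unshared peaks were compared within each list by a two-sided permutation test of the difference of medians with 100000 resamples; peaks of a list are not independent replicates, so this describes the list. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The functions were tested on simulated data: lists made from the 1132 wild-type peaks with 25% or 75% of peaks retained gave shares of 25% and 75%.

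With 1 library per genotype, a difference between genotypes has no replicate check, and no p-value was computed for one. The depth of the libraries is unknown, because the lists hold no read counts, and the number of called peaks depends on it. The input sample was not analysed here. The regions named were fixed by a rule before the data were examined: the 10 regions in all 3 lists with the highest sum of within-list score percentiles, the 5 highest in both mutants and not the wild type, and the 5 highest-scoring peaks found only in each list. The alternatives, fixed at the same time, were a reciprocal overlap of 50%, a distance of up to 500 bp, the higher-scoring 50% of each list, lists held to the 1132 highest-scoring peaks, removal of the sex chromosomes, a score threshold and merging of nearby peaks.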

Results

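PU.1 binding was mapped by ChIP-seq in splenic B cells activated for 96 h with lipopolysaccharide and interleukin-4, from mice of 3 genotypes. miR-155 is a microRNA that is induced in activated B cells and represses PU.1. In the miR-155 knockout the microRNA is absent. In the knock-in, written PU.1[155-/155-] in the labels, the PU.1 gene carries a change in its miR-155 target site. The comparison of both mutants with the wild type asks where PU.1 is bound when this repression is lost. Each genotype was represented by 1 library, so every difference between genotypes given here is a difference between single libraries without a replicate check. The read depth of these libraries is unknown.

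The wild-type B cells had 1132 PU.1 peaks, the knock-in cells 2094 and the miR-155 knockout cells 4153. The knock-in list was 1.85 times and the knockout list 3.67 times as long as the wild-type list. The peaks covered 357 kb in the wild type, 689 kb in the knock-in and 1272 kb in the knockout. Peak widths were alike in the 3 lists, with a median of 314 bp (interquartile range 257 to 364) in the wild type, 315 bp (262 to 370) in the knock-in and 296 bp (246 to 355) in the knockout. Peaks lay on all autosomes and on both sex chromosomes. Chromosome X held 16 wild-type peaks (1.41% of the list, exact 95% interval 0.81 to 2.29), 27 knock-in peaks (1.29%, 0.85 to 1.87) and 57 knockout peaks (1.37%, 1.04 to 1.77). Chromosome 6 held 4.77% of wild-type peaks (3.60 to 6.18), 5.40% of knock-in peaks (4.47 to 6.45) and 6.62% of knockout peaks (5.88 to 7.42). These intervals overlap. Chromosome 6 had the highest ratio of knockout to wild-type peak numbers, at 5.09, followed by chromosome 18 at 5.0.

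The sites bound in wild-type cells were largely called in both mutants. Of the 1132 wild-type peaks, 1061 overlapped a knockout peak (93.7%, exact 95% interval 92.2 to 95.1) and 842 overlapped a knock-in peak (74.4%, 71.7 to 76.9). Shifting the lists along the chromosomes gave a median of 0.088% and a highest value of 0.53% of wild-type peaks for the knockout list over 1000 shifts, and at most 0.353% for the knock-in list. Shifted peaks could fall anywhere up to the last called position. This background therefore does not account for sequence that tends to be called in any library. Overlapping peaks lay nearly on top of each other. The centres of overlapping wild-type and knockout peaks were a median of 33 bp apart, and those of wild-type and knock-in peaks 33.5 bp apart. Within 100 bp of each other were 94.5% of the wild-type and knockout pairs and 93.6% of the wild-type and knock-in pairs.

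In the opposite direction, 1061 of the 4153 knockout peaks overlapped a wild-type peak (25.5%, 24.2 to 26.9), which left 3092 knockout peaks with no wild-type counterpart. Of the 2094 knock-in peaks, 843 overlapped a wild-type peak (40.3%, 38.1 to 42.4) and 1251 did not. When each list was held to its 1132 highest-scoring peaks, 718 wild-type peaks were found in the knockout list (63.4%, 60.5 to 66.2) and 675 in the knock-in list (59.6%, 56.7 to 62.5).

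Joined over the 3 genotypes, the peaks formed 4750 regions, of which 822 were called in all 3 genotypes. A further 725 regions were called in both mutants and not in the wild type. The knockout shared 239 regions with the wild type alone, and the knock-in shared 20 with the wild type alone. Regions called in a single genotype numbered 2367 in the knockout, 526 in the knock-in and 51 in the wild type.

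**Figure D1:**
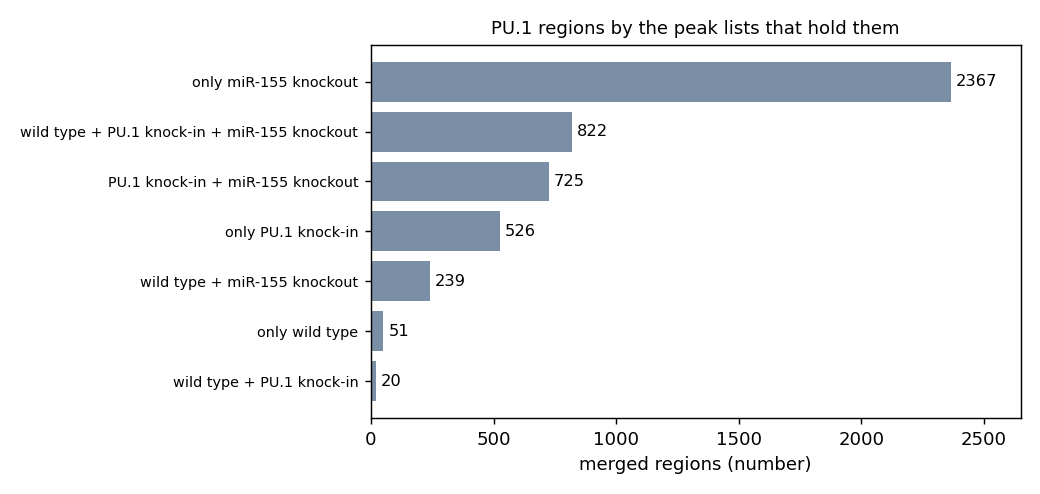
Number of merged regions (x axis) for each combination of peak lists that holds them (y axis), with 1 library per genotype; bars are counts and have no error. The 2367 regions called only in the miR-155 knockout are the largest class, followed by 822 regions in all 3 lists and 725 in both mutants.

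Regions called in all 3 genotypes were ranked by the sum of their within-list score percentiles, and the leading 10 are named here. The region with the highest score in every list lay on chromosome 2 from 127834131 to 127835338, a span of 1208 bp, with the authors' score at 926.5 in the wild type, 1069 in the knock-in and 1932 in the knockout. Scores are ranked within a list, and the sizes of these scores are not compared between lists. The next regions by combined rank lay on chromosome 9 from 96299796 to 96300346, on chromosome 2 from 35351356 to 35351911 and on chromosome 18 from 66597358 to 66597874. They were followed by regions on chromosome 9 from 48366781 to 48367193, on chromosome 5 from 98447132 to 98447670 and on chromosome 14 from 103886128 to 103886680. The last of these 10 regions were on chromosome 8 from 47680881 to 47681436, on chromosome 4 from 149940246 to 149940684 and on chromosome 14 from 70802154 to 70802745. Each of the 10 contained 1 peak per genotype and stood above percentile 98 of its list by score in all 3 genotypes. Their presence in all 3 lists and their high ranks follow from the rule that chose them. A region called in the knock-in alone, on chromosome X from 166414713 to 166418441, also stood at percentile 98.76 of the knock-in list. It was 11.84 times as wide as the median knock-in peak and lay among other wide peaks described below, so it may not be a binding site of the same kind.

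Within each list, peaks found in another genotype had higher median scores than peaks that were not. The scores of the 2 groups overlapped: regions called in the knockout alone reached 284.9, and 55.6% of the higher-scoring 50% of knockout peaks lacked a wild-type peak. Lists cut at a score threshold may give this direction whatever the genotype, so these comparisons describe the lists only. Wild-type peaks found in the knock-in had a median score of 85.0, against 60.3 for the 290 not found (permutation test, p = 1e-05). Wild-type peaks found in the knockout had a median of 78.6, against 57.8 for the 71 not found (permutation test, p = 0.0001). Knockout peaks found in the wild type had a median of 165, against 76.0 for those not found, and knock-in peaks found in the wild type 95.8 against 61.9 (permutation tests, p = 1e-05 for each). A p of 1e-05 is the smallest these permutations can give, and all 6 comparisons of this kind had p at or below 0.0001 both before and after Benjamini-Hochberg adjustment. The share of knockout peaks found in the wild type went from 2.41% (exact 95% interval 1.16 to 4.39) in the lowest-scoring 10% of the list to 87.3% (83.7 to 90.3) in the highest-scoring 10%. For knock-in peaks the same share went from 8.13% (4.81 to 12.7) to 91.9% (87.4 to 95.2). All 114 wild-type peaks of the highest-scoring class were found in both mutants.

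**Figure D2:**
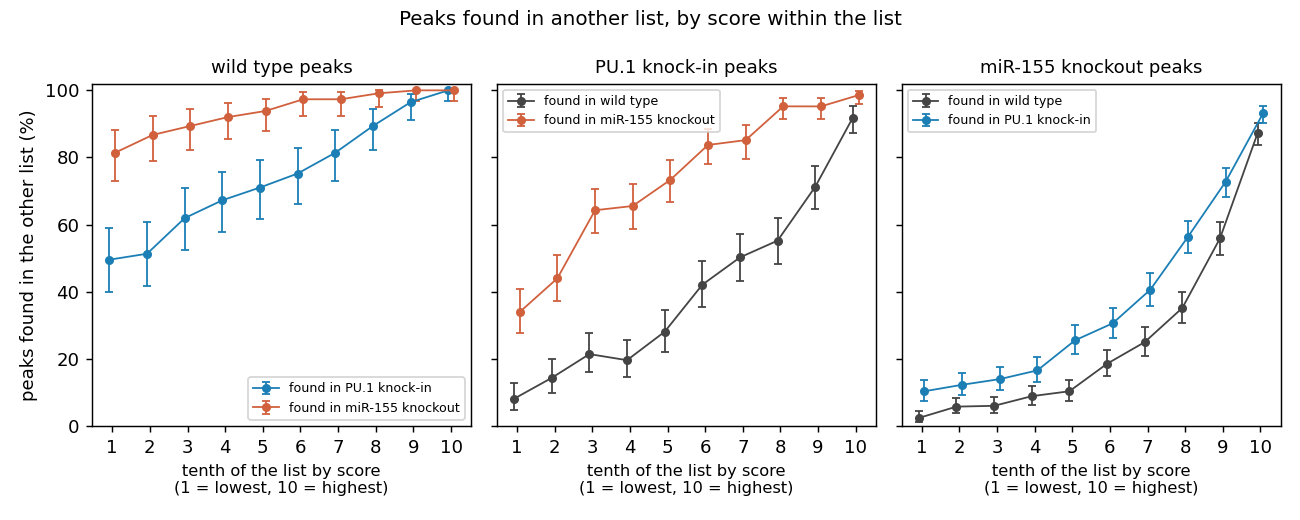
Share of each genotype's peaks found in another genotype's list (y axis, percent) by class of score within the list (x axis, 1 lowest to 10 highest), 1 panel per list; bars are exact 95% binomial intervals over peaks. The share of knockout peaks found in the wild type goes from 2.41% in the lowest class to 87.3% in the highest.

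The mutants were also compared with each other, since one lacks the microRNA and the other its target site in the PU.1 gene; the levels of PU.1 and miR-155 in these cells were not analysed here. Of the 2094 knock-in peaks, 1548 overlapped a knockout peak (73.9%, exact 95% interval 72.0 to 75.8), and 1547 of the 4153 knockout peaks overlapped a knock-in peak (37.3%, 35.8 to 38.7). The centres of overlapping pairs were a median of 37.5 bp apart. Knock-in peaks that had a wild-type counterpart were nearly all found in the knockout, at 823 of 843 (97.6%, 96.4 to 98.5). Knock-in peaks without one were found there in 725 of 1251 cases (58.0%, 55.2 to 60.7). For comparison, wild-type peaks without a knock-in counterpart were found in the knockout in 239 of 290 cases (82.4%, 77.5 to 86.6). At equal list lengths of 1132 peaks, 60.7% of knock-in peaks were found in the knockout (57.8 to 63.5), against 63.4% of wild-type peaks (60.5 to 66.2). These intervals overlap, so among these peaks the knock-in list was not detectably closer to the knockout list than the wild-type list was. The shortened knockout list ended at a score of 130.99. Regions called in both mutants and not in the wild type had a median knockout score of 104. Most of those regions were thus left out, and the comparison says little about them.

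Among the 725 regions called in both mutants and not in the wild type, the highest by combined rank lay on chromosome 10 from 51173747 to 51174218, with a score of 207.6 in the knock-in and 378.7 in the knockout. The others of the leading 5 were on chromosome 6 from 52792537 to 52792922, on chromosome 7 from 38940736 to 38941216, and on chromosome 1 from 145763624 to 145763994 and from 60998137 to 60998516. In the knockout list the 725 regions had a median score of 104, compared with 186 for the 822 regions called in all 3 genotypes. In the knock-in list the medians were 70.1 and 98.6.

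The 2367 regions called in the knockout alone had a median score of 71.8 in a list whose overall median was 88.8. The highest of them were on chromosome 10 from 94190850 to 94191245 with a score of 284.9, on chromosome 4 from 107036668 to 107037004 with 254.9 and on chromosome 19 from 37598251 to 37598599 with 247.8. They were followed by chromosome 2 from 116815753 to 116816183 and chromosome 6 from 127112911 to 127113180. Of the 416 highest-scoring knockout peaks, 347 were found in both other genotypes, 41 in the knock-in alone, 16 in the wild type alone and 12 in neither.

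The 51 regions called in the wild type alone had a median score of 57.8, with a highest score of 98.23 on chromosome 15 from 73426946 to 73427291. The next were on chromosome 6 from 108668891 to 108669140, chromosome 16 from 75919659 to 75920157, chromosome 8 from 89386089 to 89386384 and chromosome 7 from 124549902 to 124550147.

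The 526 regions called in the knock-in alone had a median score of 58.2, and the 3 highest of them were neighbours on chromosome X. They lay from 166414713 to 166418441 with a score of 282, from 166421624 to 166423337 with 201 and from 166418864 to 166421609 with 181.5. Another knock-in peak next to them, from 166409751 to 166414442, was 4692 bp wide, had the second highest score of the list at 851.7, and overlapped a peak of the wild type and of the knockout. These 4 knock-in peaks were 5.44 to 14.9 times as wide as the median peak of their list, and whether they overlie repeated sequence was not analysed here. In the wild type the overlapping peak was 697 bp wide and in the knockout 511 bp. Of peaks wider than 1000 bp, the knock-in list held 5, of which 4 were these; the wild-type list held 0 and the knockout list 1. The other knock-in regions among the leading 5 were on chromosome 3 from 86010550 to 86010927 with a score of 140.9 and on chromosome 17 from 27179669 to 27179944 with 130.8.

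**Figure D3:**
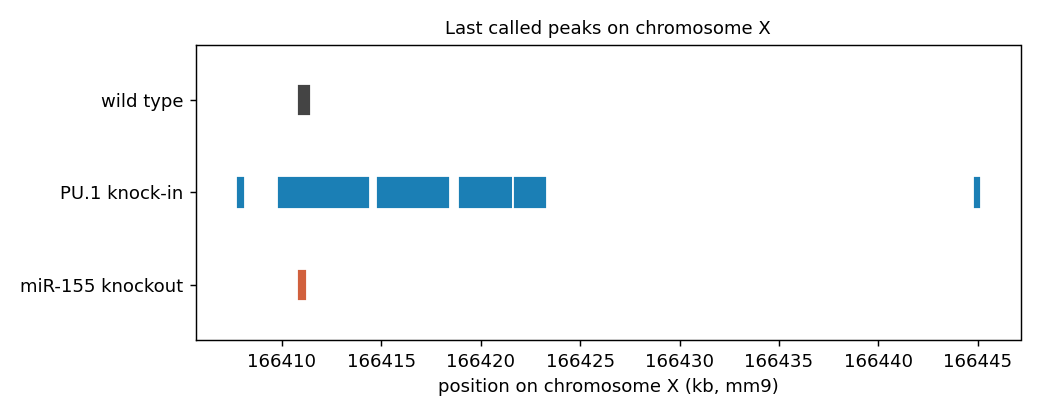
Called peaks (bars drawn to scale) on chromosome X between positions 166407662 and 166445155 (x axis in kb, mm9) in each genotype's list (y axis). The knock-in list has 6 peaks covering 13728 bp, 4 of them adjacent and up to 4692 bp wide, where the wild-type and knockout lists have 1 peak each of 697 and 511 bp.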

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

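All alternatives but 2, named as added, were fixed before the data were examined. Applying the median wild-type score of 76.6 to all lists left 566 wild-type, 947 knock-in and 2471 knockout peaks, in the same order as before. A score that grows with depth passes more peaks in a deeper library, so this setting does not check whether depth set the order. A reciprocal overlap of 50% lowered the share of wild-type peaks found in the knock-in to 70.1%, of wild-type peaks found in the knockout to 90.1% and of knock-in peaks found in the knockout to 70.7%. Holding each list to its 1132 highest-scoring peaks gave 59.6%, 63.4% and 60.7%, and the fall follows from shortening the lists that are searched. When all 3 lists, the searched one included, were reduced to their higher-scoring 50%, the share of knock-in peaks found in the knockout was 80.4%. Against the whole knockout list, 8.41% of the higher-scoring 50% of knock-in peaks lacked a counterpart, compared with 26.1% of all knock-in peaks. The rise thus came with the removal of lower-scoring knock-in peaks, and shortening the searched list worked against it. An added setting, chosen after seeing the data, held only the knock-in list to 1132 peaks, searched the whole knockout list and gave 90.4%; another left out the 4 wide knock-in peaks on chromosome X and kept 2090 peaks. The regions in all 3 lists numbered 415 with the higher-scoring 50% and 545 with lists of equal length, because fewer peaks enter, and between 801 and 821 under the other 3 alternatives. Joining peaks up to 500 bp apart and leaving out the sex chromosomes moved no share outside its interval. The higher scores of shared peaks kept their direction and their side of p = 0.05 by the permutation test in all 12 alternative comparisons, with differences of medians from 19.2 to 90.0. No paired analysis was possible because each genotype has 1 library and the labels give no replicate numbers, and for the same reason no replicate could be left out. The planned promoter, gene list and motif results and their alternatives were not run, since they need an mm9 annotation or sequence. The unknown depth limits what an absent peak shows: 93.3% of the lower-scoring 50% and 55.6% of the higher-scoring 50% of knockout peaks were absent from the wild-type list, and the lists do not tell an unbound site from one under the calling threshold.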

Other observations

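The tests below of list length and of the score of regions in both mutants were stated before their results were seen. The check for wild-type peaks missing from the longer lists was chosen after. So were the tests of the knock-in peaks without a knockout counterpart and the setting that shortened the knock-in list alone. The comparison with regions missed by the knock-in was also chosen after. Holding all 3 lists to equal length was fixed before the data were examined, but its use to ask about sites gained in both mutants was chosen after.

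PU.1 peaks also came in groups along the chromosome. With peaks up to 10 kb apart joined, 13.3% of knockout peaks lay in groups of at least 2, against 6.78% of knock-in and 6.18% of wild-type peaks. The knockout list had a group of 5 peaks on chromosome 9 from 65383061 to 65393751, where the wild type had 2 and the knock-in 3. It also had 4 peaks on chromosome 10 from 7553512 to 7572009, where the wild type and the knock-in had 1 each, and 4 on chromosome 9 from 58093930 to 58119332, where they had 2 each. Groups of 3 without any wild-type or knock-in peak were found in the knockout on chromosome 8 from 91150338 to 91161777, on chromosome 12 from 104571055 to 104581966 and on chromosome 15 from 66648636 to 66657244. A longer list gives more neighbours by itself, and this was not corrected for.

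On chromosome Y, the knock-in list had 4 peaks between 1591624 and 1642679, 1 of which was also called in the knockout. The wild type had 2 peaks elsewhere on Y, at 488880 to 489089 and at 2503243 to 2503590, and the first of these was also called in the knockout. The share of knockout peaks on chromosome 6, 6.62% in the whole list, was 4.95% among its 1132 highest-scoring peaks.

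Both mutants had longer PU.1 peak lists than the wild type. If unequal depth or enrichment of the libraries were the cause, the strong peaks of the longer lists would be in the wild-type list too and the weak ones would not. That was the case: 87.3% of the highest-scoring 10% of knockout peaks (exact 95% interval 83.7 to 90.3) and 91.9% of those of the knock-in (87.4 to 95.2) overlapped a wild-type peak, against 2.41% and 8.13% in the lowest-scoring 10%. A general rise in PU.1 occupancy in the mutants may give the same pattern, and these lists cannot separate it from depth; no PU.1 level was measured in them. Either cause would also leave nearly all wild-type peaks in the longer lists. The knockout list lacked 71 of 1132 (6.27%) and the knock-in list 290 (25.6%). Of the 566 higher-scoring wild-type peaks, 7 (1.24%) were absent from the knockout list and 65 (11.5%, exact 95% interval 8.98 to 14.4) from the knock-in list. All 114 of the highest-scoring 10% were found in both. This was met for the knockout list and only in part for the knock-in list. Read counts per library and replicate libraries would be needed.

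The 725 regions called in both mutants and not in the wild type are candidates for sites gained when PU.1 escapes miR-155. Their median score percentile in the knockout list was 25.8 points below that of the regions in all 3 lists (95% bootstrap interval 22.3 to 28.4). The 239 regions called in the wild type and the knockout but missed in the knock-in lay 24.0 points below, within that interval. The gap was thus not particular to regions missed in the wild type, and it does not tell a wild-type list that stops too early from weak sites that were gained. Each list was also held to 1132 peaks. The share of knock-in peaks found in the knockout minus that of wild-type peaks was then -2.74 percentage points, with overlapping intervals. The shortened knockout list ended at a score of 130.99, and the 725 regions had a median knockout score of 104. This setting left most of them out, so an additional set of sites common to the mutants was neither shown nor excluded. Genotype and library cannot be told apart here, because each genotype has 1 library.

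A larger part of the knock-in list (26.1%) than of the wild-type list (6.27%) had no counterpart in the knockout list, and the size of this difference depended on how the lists were matched. Searched against the whole knockout list, 8.41% of the higher-scoring 50% of knock-in peaks (exact 95% interval 6.80 to 10.3) and 1.24% of the higher-scoring 50% of wild-type peaks (0.499 to 2.53) lacked one. The knock-in list alone was then held to its 1132 highest-scoring peaks, again against the whole knockout list. Of these, 9.63% (7.97 to 11.5) lacked a counterpart, against 6.27% (4.93 to 7.85) of wild-type peaks. With all 3 lists held to 1132 the intervals overlapped, at 60.7% and 63.4% found. That setting drops knockout peaks scoring under 130.99, so it does not measure the lack of a knockout counterpart. Against the whole knockout list, the share found was lower for the knock-in in every class of score. It was 34.0% (27.6 to 40.8) against 81.4% (73.0 to 88.1) in the lowest-scoring 10%. In the highest-scoring 10% it was 98.6% (95.9 to 99.7) against 100% (96.8 to 100). These classes covered nearly the same scores in both lists. The lowest ran from 50.08 to 53.15 in the knock-in and from 50 to 53.45 in the wild type, and the highest began at 144.77 and 145.54. The knock-in list thus did not reach lower scores, but a score that grows with depth need not mean equal binding. A longer list that reaches weaker sites, binding specific to the knock-in and library-specific background therefore all stay open. For the 4 wide knock-in peaks on chromosome X, reads piling up on a repeated or amplified sequence may be the source rather than binding, which was not tested; without them the list had 2090 peaks.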
